A study of Homo sapiens with 6 samples.

How the data were processed

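Total RNA of HCT116 cells was labelled with biotin and hybridised to Affymetrix arrays, per the labels and the design text of the series. The deposited table holds 1 value per probe set and array for 49395 probe sets and 6 arrays. The authors deposited these as log2 values, as far as the values show: they run from 0.81 to 12.7, and the base of the logarithm, the background correction, the summarisation and the normalization between arrays are not given in the sources used here. If the base were another one, every fold below would change while the tests would not. The arrays have nearly equal means (4.07) but not equal quantiles, so the deposited values were not quantile normalized over all 6 arrays. Scanner files were not used here. No detection calls were used, so a dim gene cannot be told from one that is off, and a fold is the ratio of the signals as deposited. The number of arrays limits the precision.

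Probe sets were named from the platform annotation. Of the probe sets, 44988 have 1 gene, 1832 have several, 2473 have none and 102 are controls of the array. Probe sets with several genes or none were left out. Gene symbols were checked through their Entrez identifiers against the RefSeq annotation of GRCh38.p14, which found 44961 of the probe sets and changed 0 symbols. The probe set with the highest mean over the 6 arrays stood for its gene, which gave 18132 genes, 11734 of them with more than 1 probe set. Where the brightest and the next brightest probe set of a gene were both called, which was so for 5988 genes, 11.6% of the genes had opposite signs. Probe sets whose name ends in _x_at or _s_at, among them the main ones of CSF3 and NFKBIA, can hybridise with more than 1 transcript.

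CSF3 minus Ctrl was tested on the log2 values of all 3 and 3 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no filter on dim genes and no covariates, and p-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05. Values are given as mean ± SD of 3 arrays, and changes as the log2 difference ± its standard error. The 24 gene lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation and with fry, each adjusted over the 24 lists. With an estimated correlation 0 lists were called, the lowest adjusted p being 0.197. By fry, which tests whether a list's genes move on balance one way and compares them with no other genes, 18 lists were called. Each list's median was also set against 10000 random lists of the same size matched on mean level in 100 bins, as a description of these arrays. Control probe sets were compared by exact two-sided permutation tests of 3 against 3 arrays, which cannot go below a p of 0.1.

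The lists, the tests, the other settings tried and the rule for named genes were fixed before the data were examined. The rule names CSF3, CSF3R, TMEM74, RELA, NFKB1 and NFKBIA whatever their values, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap, and the 4 members of each list with the smallest p. The 92 genes named from the lists had limma adjusted p-values up to 0.000953 and standard errors from 0.047 to 0.11. The alternatives were quantile normalization of the deposited values, subtraction of array medians, leaving out the 30% dimmest genes, the mean of all probe sets of a gene, eBayes with trend and robust settings, array weights, the replicate number as a block, Student's test without moderation, a change of at least 1 on the log2 scale, and leaving out each array in turn. The comparison with level-matched lists and that with the control probe sets were added after seeing the data.

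The fit was tested on simulated data for CSF3 against Ctrl with the means and spreads of the 18132 genes, of which 200 were changed. Of 50 genes each changed by 0.25, 0.5, 1 and 2 on the log2 scale, it recovered 12%, 66%, 88% and 100%, and it called 2 unchanged genes. A list shifted by 0.3 was called by camera, and 0 of the others were. The simulated genes were drawn independently and without a shift that depends on level. The simulation therefore does not show how often camera calls unchanged lists on these arrays.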

Results

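Gene expression was measured on Affymetrix arrays in cells labelled HCT116, the name of a human colorectal carcinoma cell line. The series holds 6 arrays of total RNA, 3 from cells labelled as control (Ctrl) and 3 from cells labelled CSF3. CSF3 encodes granulocyte colony-stimulating factor, a cytokine that drives the production of neutrophils. The labels do not say whether CSF3 was added as a protein, expressed from a vector or changed in another way. They also do not say whether the 3 samples of a group came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical. The title of the series names TMEM74, autophagy and the p65 arm of NF-κB signalling, and the comparison of CSF3 with Ctrl arrays addresses how these and all other measured genes differed between the groups. The deposited table gave log2 signals for 49395 probe sets per array, and 18132 genes were tested with 1 probe set each.

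Arrays of one group were closely alike. Across probe sets, Pearson's r was 0.998 between Ctrl arrays, 0.994 to 0.995 between CSF3 arrays and 0.970 to 0.974 between the groups. The median SD of a gene was 0.061 over the Ctrl arrays and 0.103 over the CSF3 arrays (log2, n = 3 each). The distributions of the deposited values differed between groups: the lower quartile lay at 2.18 to 2.19 on the Ctrl arrays and at 2.40 to 2.43 on the CSF3 arrays, and the upper quartile at 5.63 and at 5.37 to 5.40. Dim genes therefore tended to read higher on the CSF3 arrays, with a median change of 0.31 in the dimmer part of the genes and of -0.13 in the brighter part, split at the median level.

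Control probe sets, which do not measure genes of the study, also differed between the groups. The 18 probe sets for hybridisation controls, bacterial and phage transcripts usually added after labelling, had a median of 6.82 ± 0.07 on the Ctrl arrays and 8.36 ± 0.05 on the CSF3 arrays (SD, n = 3), and all 18 were higher on the CSF3 arrays. The 24 probe sets for poly-A controls, usually added to the sample RNA before labelling, had a median of 4.09 ± 0.25 and 5.61 ± 0.03, and all 24 were higher. The gap between the 3' and the 5' probe set of GAPDH, a common sign of RNA integrity and of how far labelling proceeds, was 0.306 ± 0.007 on the Ctrl arrays and 0.682 ± 0.003 on the CSF3 arrays. That of ACTB was 1.34 ± 0.03 and 1.94 ± 0.02. Each of these 4 differences had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 arrays can give. All directions below are relative to the bulk of each array as the authors scaled it, where the median change of all genes was 0.16. Only 16 genes had a change above the median shift of the hybridisation controls, 1.53.

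**Figure D1:**
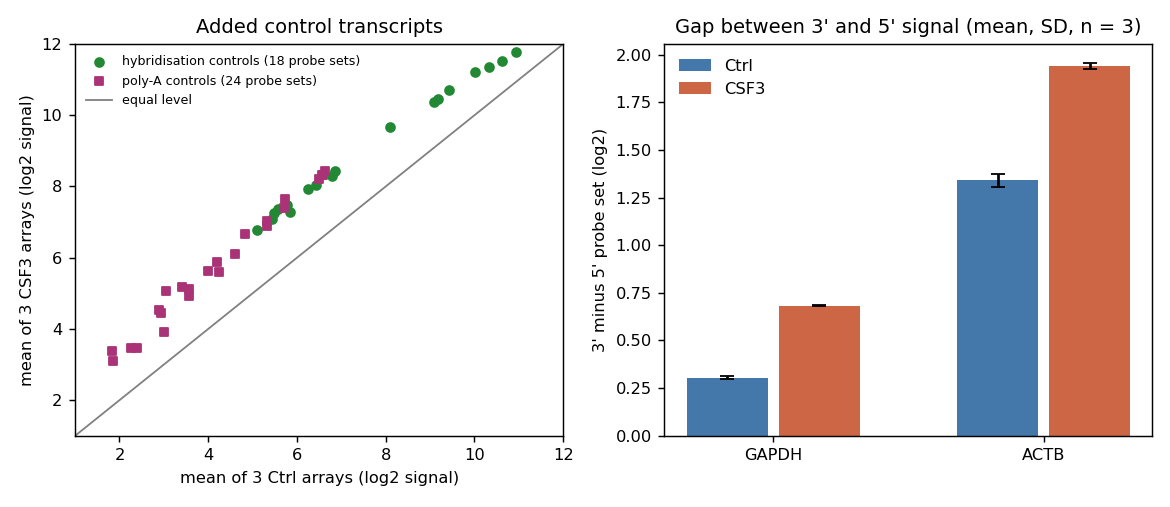
Left, each point is a control probe set, with its mean over 3 Ctrl arrays on the x axis and over 3 CSF3 arrays on the y axis (log2 signal); all 18 hybridisation and 24 poly-A control probe sets lie above the line of equal level. Right, bars give the mean and SD (n = 3) of the 3' minus 5' signal (log2) of GAPDH and ACTB, which was wider on the CSF3 arrays (0.682 against 0.306 for GAPDH).

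CSF3, the gene the groups are named for, read higher in the CSF3 group. Its brightest probe set had a log2 signal of 4.83 ± 0.30 on the Ctrl arrays and 5.96 ± 0.04 on the CSF3 arrays (SD, n = 3), a 2.18-fold difference (log2 change 1.12 ± 0.14 SE, limma adjusted p = 0.000371). Its other 2 probe sets gave log2 changes of 1.77 and 0.59, so all 3 rose and their sizes differed. The gene ranked 65th of all genes by its change. CSF3R, the receptor of the cytokine, rose 1.68-fold on its brightest probe set (0.75 ± 0.06, limma adjusted p = 4.96e-05), whereas its dimmer probe set changed by 0.06 ± 0.06. TMEM74, which encodes a lysosomal membrane protein linked to autophagy, rose from 2.18 ± 0.17 to 3.10 ± 0.14 (log2 change 0.92 ± 0.11, limma adjusted p = 0.000272). Without detection calls its signal is not known to lie above background on the arrays of either group, so no fold is given for it.

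NFKBIA, which encodes the NF-κB inhibitor IκBα and is itself induced by NF-κB, rose 3.96-fold from 7.13 ± 0.01 to 9.11 ± 0.06 (1.99 ± 0.05, limma adjusted p = 7.89e-06). Its other probe sets gave 1.90 and 1.42 on the log2 scale. RELA, which encodes p65, read 7.16 ± 0.01 and 7.20 ± 0.03 on its brightest probe set, and this difference of 0.04 ± 0.05 did not pass the test (limma adjusted p = 0.475). Its 2 dimmer probe sets fell, with log2 changes of -0.82 and -0.54, and after quantile normalization the brightest one rose by 0.25 (limma adjusted p = 0.00312), so RELA has no settled direction. NFKB1, which encodes the p105 precursor of p50, fell by 0.33 ± 0.08 (limma adjusted p = 0.00885), a call lost after quantile normalization, where the change was -0.07 (limma adjusted p = 0.530).

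**Figure D2:**
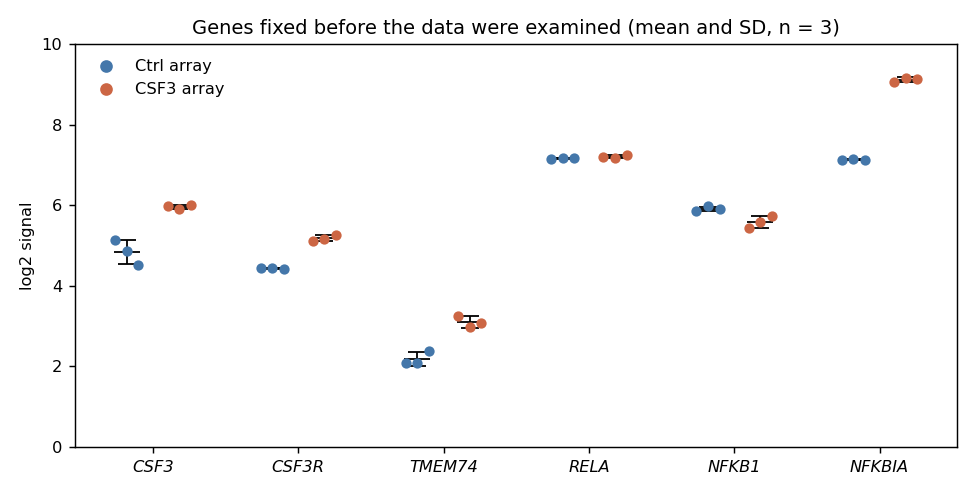
Log2 signal of CSF3, CSF3R, TMEM74, RELA, NFKB1 and NFKBIA on each Ctrl and CSF3 array, with the group mean and SD (n = 3). NFKBIA rose from 7.13 to 9.11 and CSF3 from 4.83 to 5.96, while the brightest probe set of RELA read 7.16 and 7.20.

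Across all genes, 8227 rose and 4921 fell on the CSF3 arrays at a limma adjusted p under 0.05, which together are 72.5% of the 18132 tested. With the 30% dimmest genes left out, 4767 rose and 4883 fell, so the excess of rises lay among dim genes. Most changes were small: 117 genes rose and 611 fell by at least 2-fold, or 193 and 330 after quantile normalization. The 12 genes with the largest rise among those whose groups did not overlap were CXADR, GADD45G, ZNF532, NFKBIA, POM121L8P, FGF7P3, RUNX1T1, FOXD4L5, GADD45B, ID2, SNORA33 and USP41P, with log2 changes from 2.22 to 1.70. CXADR, the receptor for coxsackievirus and adenovirus, rose by 2.22 ± 0.07, from 4.03 ± 0.02 to 6.24 ± 0.11, on its brightest probe set, while its 4 probe sets ranged from 0.18 to 2.22. GADD45G and GADD45B, stress-induced growth arrest genes, rose by 2.14 ± 0.09 and 1.84 ± 0.06. ID2, an inhibitor of basic helix-loop-helix transcription factors, rose by 1.72 ± 0.09. RUNX1T1, a transcriptional corepressor, rose by 1.85 ± 0.09, and the small nucleolar RNA gene SNORA33 by 1.71 ± 0.16. ZNF532, a zinc finger gene, rose by 2.01 ± 0.11. The probe sets of RUNX1T1 ranged from 0.0084 to 1.85 and those of ZNF532 from 0.26 to 2.01, so these sizes rest on single probe sets. POM121L8P, FGF7P3, FOXD4L5 and USP41P belong to families of near-identical copies, so their probe sets may read other members as well. The highest limma adjusted p of these genes was 9.48e-05.

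The 12 genes with the largest fall were ATP10D, CFAP263, STEAP2, SLC2A10, WDR35, ZKSCAN1, MCOLN3, ADGRG6, ADGRA3, TRIM2, ITPRIPL2 and TTN, with log2 changes from -2.17 to -1.85 and a highest limma adjusted p of 0.000118. ATP10D, of the phospholipid flippase family, fell by 2.17 ± 0.06, with 5.86 ± 0.04 on the Ctrl and 3.70 ± 0.07 on the CSF3 arrays. CFAP263 and WDR35, which act in cilia, fell, with log2 changes of -2.14 ± 0.08 and -1.99 ± 0.13. STEAP2, a metalloreductase, fell by 2.02 ± 0.08, and SLC2A10, a glucose transporter, fell by 2.01 ± 0.06. MCOLN3, an endolysosomal cation channel, fell by 1.93 ± 0.11. The adhesion receptors ADGRG6 and ADGRA3 fell, with log2 changes of -1.92 ± 0.07 and -1.90 ± 0.11. TTN, which encodes the giant muscle protein titin, fell by 1.85 ± 0.18. Other probe sets of these genes did not always agree: of the 18 genes in both groups of 12 that have several probe sets, 6 had probe sets with changes of both signs, namely ATP10D, CFAP263, SLC2A10, WDR35, ZKSCAN1 and ADGRG6.

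**Figure D3:**
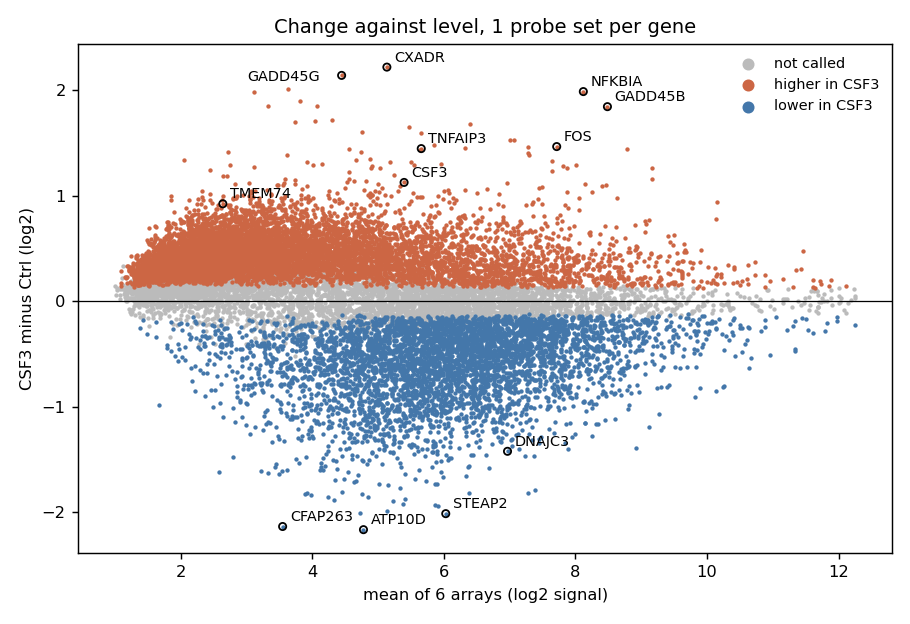
Each point is a gene, with its mean log2 signal over 6 arrays on the x axis and the CSF3 minus Ctrl difference (log2) on the y axis; colours mark genes higher or lower at a limma adjusted p under 0.05. Dim genes lie mostly above 0, and NFKBIA and GADD45B stand at 1.99 and 1.84 among brighter genes.

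Targets of NF-κB moved mostly upward. Of the 48 measured genes of this list, 32 rose, 6 fell and 10 did not pass the test, both over all genes tested and adjusted over the list alone, against 45.4% of all genes rising and 27.1% falling. After NFKBIA the members with the smallest p were NFKBIE, which encodes another inhibitor of NF-κB (0.96 ± 0.05), TNFAIP3, which encodes the feedback inhibitor A20 (1.45 ± 0.08), and CXCL2, a neutrophil-attracting chemokine (1.44 ± 0.08). The list's median change was 0.34, and it ranked above other genes by camera (adjusted p = 0.00652, adjusted p = 0.197 with an estimated correlation, which was -0.0017). On the same arrays the GAPDH gap was 0.682 against 0.306. The 28 measured components of the NF-κB pathway went the other way, with 6 higher, 16 lower and 6 not called, adjusted over the list alone too. TRAF5, MAP3K7, TRAF3 and TAB2, adaptors and kinases upstream of NF-κB, fell, with log2 changes of -0.87 ± 0.05, -1.07 ± 0.07, -0.87 ± 0.07 and -0.69 ± 0.07. The median of the components was -0.26 (camera adjusted p = 0.00503, adjusted p = 0.197 with an estimated correlation), and this call was lost after quantile normalization (median -0.06, camera adjusted p = 0.198).

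Genes of CSF3 receptor signalling went both ways. Of 18 measured, 5 rose, 7 fell and 6 did not pass the test, adjusted over the list alone too (camera adjusted p = 0.337), and the list's median was -0.02 as deposited and 0.13 after quantile normalization. By fry the list moved downward on balance as deposited (adjusted p = 0.00218) and upward after quantile normalization (adjusted p = 0.0326). Besides CSF3R, the members with the smallest p were PTPN11, the phosphatase SHP2 (-1.12 ± 0.06), JAK1 (-0.70 ± 0.06) and GAB2 (-0.58 ± 0.05). The PTPN11 call was lost when all its probe sets were averaged (-0.06, limma adjusted p = 0.275). Among 25 targets of STAT3, a transcription factor activated by the CSF3 receptor, 14 rose and 8 fell, or 15 and 8 adjusted over the list alone. PIM1, a kinase gene, rose by 0.90 ± 0.05, JUNB by 0.87 ± 0.05 and BCL6 by 0.88 ± 0.06, and CCND1, which encodes cyclin D1, fell by 0.97 ± 0.05. The list's median was 0.37 and camera did not call it (adjusted p = 0.598). Of the 27 MAPK output and immediate early genes, 14 rose and 8 fell, adjusted over the list alone too (camera adjusted p = 0.655). FOS and JUNB rose, by 1.46 ± 0.05 and 0.87 ± 0.05, and SPRED2, an inhibitor of this pathway, and CCND1 fell, with log2 changes of -1.12 ± 0.06 and -0.97 ± 0.05. Interferon-stimulated genes were also split, with 14 of 39 higher and 11 lower, adjusted over the list alone too (camera adjusted p = 0.891). IRF1, XAF1 and ISG15 rose by 1.59 ± 0.08, 0.78 ± 0.06 and 0.69 ± 0.06, and HERC6 fell by 1.30 ± 0.10. The median of the interferon list was 0.12, while camera's direction, which did not pass, was below other genes.

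Autophagy genes fell more often than they rose as deposited, while after quantile normalization 21 rose and 20 fell. Of 57 measured, 16 rose, 29 fell and 12 did not pass the test, adjusted over the list alone too. The members with the smallest p all fell: ATG2B, which encodes a lipid transfer protein of the growing autophagosome (-1.69 ± 0.07), MAP1LC3C (-1.18 ± 0.05), VMP1 (-0.99 ± 0.05) and DRAM2 (-0.69 ± 0.05). MAP1LC3B, whose protein is the usual marker of autophagosomes, rose by 0.46 ± 0.05 (limma adjusted p = 0.000249). SQSTM1, which encodes the cargo receptor p62, fell by 0.40 ± 0.06 (limma adjusted p = 0.00125). Both were chosen for mention after their values were seen, and their RNA levels measure neither the proteins nor autophagy itself. The list's median was -0.18 as deposited (camera adjusted p = 0.00636, adjusted p = 0.238 with an estimated correlation) but 0.032 after quantile normalization, where the call was lost (camera adjusted p = 0.349). Among level-matched random lists, whose median was -0.096, it lay at percentile 15.5, or 23.1 after quantile normalization. The median thus does not stand out from genes of similar level. Of the 40 measured genes of the lysosome and of the network of TFEB, its transcriptional regulator, 9 rose and 24 fell, adjusted over the list alone too. FNIP1, a regulator of nutrient sensing at the lysosome, fell by 1.52 ± 0.06, the lysosomal thioesterase gene PPT1 fell by 1.07 ± 0.06, and the cathepsin genes CTSL and CTSB had log2 changes of -0.91 ± 0.05 and -0.82 ± 0.05. The median was -0.26 (camera adjusted p = 0.000351, adjusted p = 0.197 with an estimated correlation), and -0.07 after quantile normalization (camera adjusted p = 0.0438). It lay at percentile 3.99 of level-matched random lists, or 6.50 after quantile normalization, and the wider gaps of GAPDH and ACTB were on the same CSF3 arrays.

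The endoplasmic reticulum list fell furthest. Of its 24 genes, 20 fell and 2 rose, or 20 and 3 adjusted over the list alone, with a median of -0.65. DNAJC3, a co-chaperone gene, fell by 1.42 ± 0.06 and the chaperone gene HYOU1 fell by 1.13 ± 0.05. EDEM1, which acts in the disposal of misfolded proteins, fell by 1.01 ± 0.05, and MANF, which encodes a secreted stress factor, fell by 0.91 ± 0.05. By camera the adjusted p was 1.29e-07, and adjusted p = 0.197 with an estimated correlation. After quantile normalization 19 fell and 3 rose, with a median of -0.51. The wider gaps of GAPDH and ACTB were on the same CSF3 arrays as these falls. Targets of ATF4 and the integrated stress response were divided, with 15 of 31 higher and 11 lower, adjusted over the list alone too (camera adjusted p = 0.737). ATF3, a stress-induced transcription factor gene, rose by 1.28 ± 0.05. The cystine transporter gene SLC7A11, the tryptophanyl-tRNA synthetase gene WARS1 and SHMT2 of serine metabolism fell, with log2 changes of -0.95 ± 0.05, -0.72 ± 0.05 and -0.64 ± 0.06. In this list the median was 0.09, while camera's direction, which did not pass, was below other genes. Of 30 targets of p53, 13 rose and 8 fell, or 13 and 7 adjusted over the list alone (camera adjusted p = 0.655). GADD45B, GADD45A and SESN2 rose, by 1.84 ± 0.06, 0.94 ± 0.05 and 0.46 ± 0.05, and the repair gene XPC fell by 0.63 ± 0.07. Of 22 antioxidant genes regulated by NRF2, 6 rose and 11 fell, or 7 and 11 adjusted over the list alone (camera adjusted p = 0.166). SLC7A11, SRXN1, TKT and GCLC fell, with log2 changes of -0.95 ± 0.05, -0.58 ± 0.05, -0.53 ± 0.05 and -0.91 ± 0.10.

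Genes of proliferation went both ways. In the list of DNA replication and G1/S, 11 of 41 rose and 15 fell, adjusted over the list alone too (camera adjusted p = 0.343, or 0.0400 with all probe sets averaged), and the median of -0.0064 turned to 0.18 after quantile normalization. MCM6 and POLA1 fell, with log2 changes of -0.72 ± 0.06 and -0.72 ± 0.08, and E2F2 and CCNE1 rose by 0.70 ± 0.07 and 0.48 ± 0.05. In the list of mitosis and G2/M, 15 of 39 rose and 11 fell, adjusted over the list alone too (camera adjusted p = 0.598), and the median of -0.02 turned to 0.22 after quantile normalization. CKS2, AURKB and CDC20 rose by 0.75 ± 0.05, 0.47 ± 0.05 and 0.45 ± 0.06, and the kinesin gene KIF11 fell by 0.57 ± 0.06. The direction of fry for this list, upward against the median as deposited, did not pass its test (adjusted p = 0.260). Ribosome biogenesis genes fell more often, with 20 of 29 lower and 5 higher, adjusted over the list alone too. UTP4 and BOP1 fell, with log2 changes of -0.69 ± 0.05 and -0.56 ± 0.05, while POLR1C and NOP56 rose by 0.71 ± 0.05 and 0.73 ± 0.05. Their median was -0.29 (camera adjusted p = 0.00179, adjusted p = 0.428 with an estimated correlation), and the call was lost after quantile normalization (median -0.11, camera adjusted p = 0.172). The wider gaps of GAPDH and ACTB were on the same CSF3 arrays.

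No metabolic list was called by camera. Of 34 oxidative phosphorylation genes, 10 rose and 15 fell, or 12 and 15 adjusted over the list alone (camera adjusted p = 0.0880), with a median of -0.08 that turned to 0.048 after quantile normalization. By fry this list moved downward on balance as deposited (adjusted p = 0.00888) and upward after quantile normalization (adjusted p = 0.0101). SDHD, UQCRC1, ATP5F1C and UQCRC2, of the respiratory complexes, fell, with log2 changes of -0.86 ± 0.06, -0.65 ± 0.05, -0.69 ± 0.06 and -0.48 ± 0.05. Of 30 hypoxia and glycolysis genes, 9 rose and 10 fell, adjusted over the list alone too (camera adjusted p = 0.655). ADM, which encodes the peptide adrenomedullin, and ANKRD37 rose by 1.11 ± 0.05 and 0.61 ± 0.06, and the pyruvate kinase gene PKM and P4HA1 fell, with log2 changes of -1.27 ± 0.08 and -0.78 ± 0.06. Of 18 cholesterol synthesis genes, 7 rose and 4 fell, adjusted over the list alone too (camera adjusted p = 0.891), with a median of 0.01 that was -0.0097 when array medians were subtracted. MVK, MSMO1 and EBP rose by 0.57 ± 0.07, 0.44 ± 0.06 and 0.31 ± 0.05, and TM7SF2 fell by 0.80 ± 0.06. The medians of the hypoxia and cholesterol lists were above 0, while camera's direction, which did not pass, was below other genes for both.

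Epithelial and mesenchymal genes did not move as opposites. On the Ctrl arrays the epithelial genes CDH1 and EPCAM read 2.20 and 3.63, and the mesenchymal genes AXL, ZEB1 and VIM 9.81, 8.90 and 8.38. Others went the other way, such as the epithelial KRT18 at 7.26 and the mesenchymal CDH2 at 3.49. The low CDH1 and EPCAM signals beside high ZEB1 and VIM go against the epithelial identity that the label of a carcinoma line implies. Those of KRT18 and CDH2 go with it. The identity of the cells rests on the labels and was not tested. Of 28 epithelial genes, 14 rose and 6 fell, adjusted over the list alone too (camera adjusted p = 0.934). Their median was 0.24, and fry's direction, which was downward, did not pass its test (adjusted p = 0.504). The junction genes DSP, TJP1 and DSG2 and the keratin gene KRT8 fell, with log2 changes of -1.04 ± 0.06, -0.83 ± 0.05, -1.01 ± 0.07 and -1.32 ± 0.09. Of 24 mesenchymal genes, 16 rose and 4 fell, adjusted over the list alone too (camera adjusted p = 0.343), or 10 and 4 after quantile normalization. The median level was 3.30 for the mesenchymal and 3.68 for the epithelial list, below the median gene level of 4.42 on the Ctrl arrays. The median changes lay at percentiles 85.1 and 44.9 of level-matched random lists, or 63.2 and 79.8 after quantile normalization. Neither count of rises thus stands out from genes of similar level. SNAI1, a repressor of E-cadherin, rose by 1.48 ± 0.07, while ZEB1, the intermediate filament gene VIM and the receptor kinase gene AXL fell, with log2 changes of -1.17 ± 0.05, -0.91 ± 0.05 and -1.07 ± 0.07. Of 21 Wnt targets, 10 rose and 4 fell, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.622). NKD1, BMP4 and the stem cell marker gene LGR5 rose, by 0.49 ± 0.05, 0.45 ± 0.05 and 0.59 ± 0.08, and CCND1 fell.

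Markers of intestinal differentiation and of other cell types, most of them dim, read higher on the CSF3 arrays. Of 27 intestinal genes, 21 rose and 1 fell, or 22 and 1 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.00503, adjusted p = 0.197 with an estimated correlation). KLF4, CDH17, CEACAM5 and GPA33 rose by 1.20 ± 0.07, 1.05 ± 0.11, 0.62 ± 0.07 and 0.72 ± 0.09. Of 21 blood cell markers, 13 rose and 1 fell, adjusted over the list alone too, with a median of 0.30 (camera adjusted p = 0.0591), and FCER1G, CD3G, AIF1 and HBB rose by 0.70 ± 0.06, 0.55 ± 0.07, 0.64 ± 0.08 and 0.50 ± 0.07. Of 19 markers of fibroblasts and endothelium, 12 rose and 1 fell, adjusted over the list alone too, with a median of 0.35 (camera adjusted p = 0.0306, adjusted p = 0.197 with an estimated correlation). COL1A2, CDH5, PDGFRA and PECAM1 rose by 0.95 ± 0.08, 0.41 ± 0.05, 0.59 ± 0.08 and 0.75 ± 0.10. The 341 olfactory receptor genes, measured beside them as genes that most cells leave silent and chosen after the data were seen, had a median change of 0.45. After quantile normalization neither the intestinal list nor the fibroblast and endothelium list was called (camera adjusted p = 0.172 and 0.455).

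**Figure D4:**
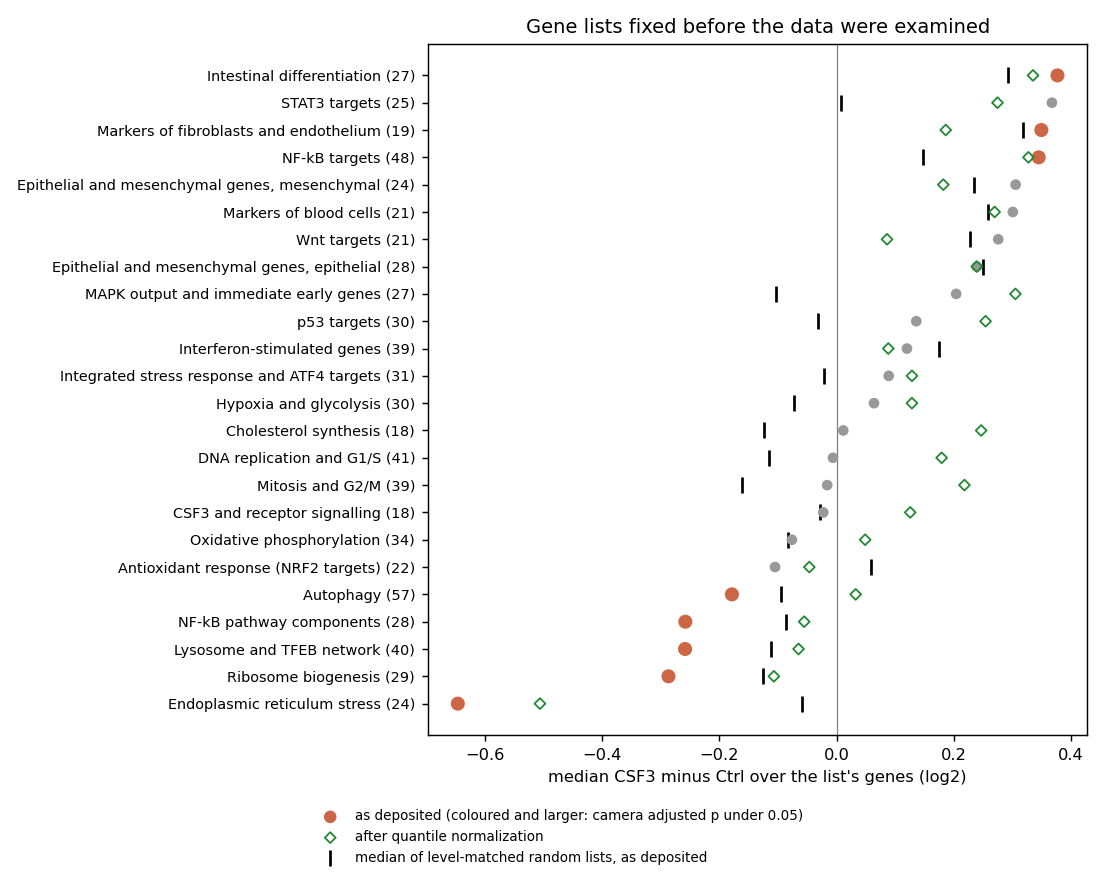
Median CSF3 minus Ctrl difference (log2, x axis) over the genes of each of 24 lists, with the number of measured genes in brackets. Filled points give the values as deposited, coloured for the 8 lists called by camera, diamonds those after quantile normalization, and bars the median of random lists of matched level; the endoplasmic reticulum list stands at -0.65, and the autophagy list lies at -0.18 as deposited but at 0.032 after quantile normalization.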

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

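The gene counts after quantile normalization and under other splits of the arrays were planned, and the other tests in this part were chosen after the values had been seen.

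Some signals outside the gene comparison differed between the groups. The control probe sets are of interest because they carry no biology of the cells: the hybridisation controls read higher on the CSF3 arrays by 1.53 and the poly-A controls by 1.52 on the log2 scale (medians per array). The 3' to 5' gap was wider there by 0.376 for GAPDH and by 0.600 for ACTB. The probe set for the Alu repeat read higher by 0.485 and that for the 5' part of 28S ribosomal RNA by 1.92. For all 6 the arrays of the groups did not overlap, which gives an exact permutation p of 0.1, the smallest these arrays allow. The median of 26 background probe sets of varying GC content read 1.39 ± 0.02 on the Ctrl and 1.42 ± 0.03 on the CSF3 arrays (exact permutation p = 0.3).

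The first pattern weighed is the rise of the added control transcripts. After quantile normalization the shift of the hybridisation controls was 1.70, which argues against the unequal distributions of the deposited values as its cause. Whether scaling of the bulk of the arrays made the shift stays undecided. Quantile normalization aligns the bulk again, so such a shift would remain after it. A lower share of mRNA in the RNA of the CSF3 cells would move the poly-A controls more than the hybridisation controls, if both were added in the usual way. At similar levels, however, their shifts differed by 0.056 (1.72 over 8 and 1.67 over 10 probe sets, with SDs of 0.10 and 0.11). Less labelled sample RNA per hybridisation control on the CSF3 arrays would by itself move only these controls, since poly-A controls are labelled with the sample if added in the usual way. The poly-A shift of 1.72 argues against it as the whole cause. Less sample RNA relative to both kinds of control stays open, since the 2 shifts are themselves the pattern and no other value tests it.

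The second pattern is that 72.5% of the genes passed the test. The narrower spread of values on the CSF3 arrays is argued against as the whole cause, since 10744 genes were called after quantile normalization, 7107 higher and 3637 lower, and 9021 genes were called in the same direction both ways. A difference in RNA integrity or labelling between the groups cannot be told apart from an effect of CSF3 for these counts: the GAPDH gap differed by 0.376 with SDs under 0.01, and no array of either group has the gap of the other. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 8227 higher and 4921 lower genes by limma, and the highest other split 0 of each. Each other split mixes arrays of both groups, which puts the group difference into its spread, so its 0 calls decide nothing about chance.

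The third pattern is the rise of NF-κB targets, for which a general rise of dim genes is argued against as the whole cause, since the list's median of 0.34 lay at percentile 100 of level-matched random lists, whose median was 0.15. RNA of blood cells in the CSF3 samples stays open: the 21 blood cell markers, 4 of them above the median gene level, lay at percentile 73.5 of their own matched lists, or 91.8 after quantile normalization, and of the markers of such cells PTPRC (1.42 and 1.66 on Ctrl and CSF3 arrays) and LAPTM5 (3.39 and 3.55) did not pass the test. LYZ (1.71 and 1.99), TYROBP (4.93 and 5.23), CORO1A (4.70 and 5.12) and FCER1G (2.23 and 2.93) rose by 0.29, 0.30, 0.41 and 0.70, where the olfactory receptor genes had a median of 0.45. An effect of CSF3, which the design names, and a response of the cells to handling before RNA extraction also remain open and were not tested.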

How the results depend on the processing

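Of the values of the 118 named genes under the alternatives, 1524 of 1528 kept their direction and their side of the threshold, the exceptions being RELA and NFKB1 under quantile normalization and RELA (-0.44) and PTPN11 with all probe sets averaged. For the lists, 317 of 360 values did so, 16 lost their call, 14 gained one and 13 changed sign. Most named genes were chosen for a large change or a small p in the same data, so few of their calls could be lost. Of the gene values that stayed the same, 708 came from leaving out an array. Over all genes, 9021 of the 13148 calls were made in the same direction after quantile normalization. Under quantile normalization the number of lists called was 3, the autophagy median was 0.032, and the medians of 4 lists not called turned: CSF3 receptor signalling 0.13, G1/S 0.18, mitosis 0.22 and oxidative phosphorylation 0.048. Without the dimmest genes 4767 genes rose and 4883 fell, against 8227 and 4921 with them. The excess of rises over falls thus lay among the dimmest genes. In this setting 4 lists were called, the autophagy call was lost (-0.18) and the interferon list stood at -0.0081. TMEM74, CEACAM5, FCER1G, PDGFRA, CDH5 and COL1A2 were not tested there. With a change of at least 1 required, 117 genes rose and 611 fell, or 193 and 330 after quantile normalization. With an estimated correlation 0 lists were called, against 8 by camera as planned, 24 by the mixed test of fry and 18 by its test of one direction. The medians of 0.34 for NF-κB targets and -0.18 for autophagy thus lost their calls. The estimated correlation was -0.0017 for the NF-κB targets, below the preset 0.01, and 0.028 for autophagy. A higher correlation between its genes therefore does not explain the lost call of the NF-κB targets. Set against level-matched lists, 4 lists lay outside the middle 95% of values, namely NF-κB targets, STAT3 targets, MAPK output and endoplasmic reticulum. Above the shift of the hybridisation controls lay 16 genes. Smaller turns were cholesterol synthesis at -0.0097 with array medians subtracted and -0.014 with probe sets averaged, where hypoxia stood at -0.031. The cause of these changes was not tested except where named.

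Leaving out each array in turn, 6948 to 7940 genes rose, 4428 to 4951 fell and 8 to 9 lists were called. CSF3 ranged from 0.97 to 1.27, TMEM74 from 0.85 to 1.02, the NF-κB median from 0.32 to 0.36 and the autophagy median from -0.18 to -0.14. Medians near 0 turned for G1/S without Ctrl replicate 3 (range -0.030 to 0.010), cholesterol synthesis without CSF3 replicate 1 (-0.028 to 0.10), mitosis without CSF3 replicate 2 (-0.099 to 0.033) and CSF3 receptor signalling without CSF3 replicate 3 (-0.062 to 0.019). The blood cell list was called without Ctrl replicate 3 (adjusted p = 0.0431), with the replicate block (0.0392) and with probe sets averaged (0.0235), where G1/S was called too (median -0.092, adjusted p = 0.0400). Of the 10 splits of the arrays, 2 called 8 or more lists, the real one with 8 and the highest other also with 8. The splits are too few for a share under 0.05. Each other split also keeps part of the group difference, so its list calls do not measure chance. The other split with 8 lists had an NF-κB median of 0.15, against 0.34 in the real one. With the replicate number as a block 8086 genes rose, 4782 fell and 9 lists were called. Arrays of one number deviated together only weakly (r of 0.038, 0.030 and 0.027), though 6 of 6 correlated best with their own number, a hint from the data and not from the design. The choice between offsets for linear values did not apply, since the deposited values are on a log scale. No depth is recorded for arrays, and without detection calls the dimmest genes have no limit of detection.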

Other observations

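The tests on early response, small nucleolar RNA, olfactory receptor and intestinal genes were chosen after their values had been seen, as were all camera tests of added lists, while the comparison of secretory genes with level-matched lists was set before their values were seen. Early response genes, which rise within minutes to hours of many stimuli, mostly rose on the CSF3 arrays. Of 26 measured, 23 rose and 2 fell, with a median of 0.81, or 0.96 after quantile normalization, and 15 of them also stand in the lists above. KLF10 rose by 1.47 ± 0.05, CSRNP1 by 1.53 ± 0.06, ARC by 1.43 ± 0.11, NR4A1 by 1.39 ± 0.07 and SGK1 by 1.26 ± 0.06, whereas MYC and MCL1 fell, with log2 changes of -0.35 ± 0.05 and -0.33 ± 0.05. The median lay at percentile 100 of level-matched random lists (camera adjusted p = 8.04e-07, adjusted p = 0.0709 with an estimated correlation, both over 4 added lists). After quantile normalization the camera adjusted p with an estimated correlation was 0.00662. Since the genes were chosen for their rise, these values do not test it. An effect of CSF3, medium change, harvest and a difference in RNA integrity or labelling all stay open. On the same arrays the GAPDH gap was 0.682 against 0.306.

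Most genes of the secretory pathway fell. Of 53 measured, which share 1 gene with the lists above, 38 fell, 5 rose and 10 did not pass the test, with a median of -0.34, or -0.21 after quantile normalization. STT3B, of the oligosaccharyltransferase, fell by 1.35 ± 0.06, TMED10, a cargo receptor gene, fell by 1.15 ± 0.05, and DDOST fell by 0.87 ± 0.05, while SEC24A of the COPII coat rose by 1.05 ± 0.08. The median lay at percentile 0.06 of level-matched lists, which goes with a fall beyond their level. By camera the adjusted p was 7.03e-10, or 0.0709 with an estimated correlation. With an estimated correlation and after quantile normalization it was 0.00662. The endoplasmic reticulum list lay at percentile 0. On the same arrays the 3' to 5' gap was 0.682 against 0.306 for GAPDH and 1.94 against 1.34 for ACTB.

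Olfactory receptor genes, which most cells leave silent, rose as well, though their silence in these cells was not tested. Of 341 olfactory receptor genes 295 rose and 0 fell by limma, with a median of 0.45, or 0.27 after quantile normalization, and at percentile 100 of matched lists, while the background probe sets differed by 0.03. The medians were 0.30 and 0.35 for the blood list and the fibroblast and endothelium list, and 0.27 and 0.19 after quantile normalization, so a general rise of silent genes may account for both. For the intestinal list this stays open: its median of 0.38 was lower than that of the olfactory receptor genes as deposited, but 0.33 was higher after quantile normalization, where it lay at percentile 99.7 of matched lists, against 92.3 as deposited. Of the 341, 9 had a larger change than TMEM74 (0.92), whose rise lay at percentile 99.0 of the 500 genes nearest to it in level. The signal of TMEM74 itself lay within the range of these 341 genes, of which 179 were brighter on the Ctrl and 109 on the CSF3 arrays. Its rise therefore does not show that the gene is expressed in either group. CSF3 lay at percentile 99.8 of its own neighbours. Of 48 small nucleolar RNA genes 38 rose and 1 fell, with a median of 0.45 at percentile 100 of matched lists, or 0.25 after quantile normalization. The olfactory receptor genes had nearly the same medians, so the medians show nothing particular to small nucleolar RNA genes. Single members differed: SNORA33, SNORA72 and SNORA84 rose by 1.71 ± 0.16, 1.65 ± 0.07 and 1.60 ± 0.10, and SNORA70C had a log2 change of -0.43 ± 0.08. These members were picked after their values were seen, so they do not test a rise of the family.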
